A study of Mus musculus with 2 samples.

How the data were processed

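The data were 2 single-cell libraries of mouse liver leukocytes, 1 per group: Ctrl from uninjured mice and RES from mice whose liver fibrosis had resolved. Per the labels' protocols, liver mononuclear cells were taken from a Histopaque gradient, the cells of 5 mice were pooled for each library, cells positive for CD45 and CD11b were sorted, and 10x 3′ droplet libraries were sequenced on an Illumina instrument. The values deposited by the authors are raw UMI counts per gene and cell barcode, without normalization, and the other deposited files hold names of genes and barcodes. The file headers name Cell Ranger 3.1.0, and the submitters' processing notes name bcl2fastq and Cell Ranger with the mm10 build. The gene annotation used for counting was not given in the sources used here. The deposited barcodes had already been called as cells, and the lowest had 500 UMIs in each library. Each matrix has 31053 genes. No deposited annotation of cell types was used here.

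Everything from the counts onward was computed for this re-analysis. Barcodes with at least 200 genes and at most 10% mitochondrial UMIs were kept. This left out 245 Ctrl and 121 RES barcodes, of which 244 and 119 exceeded the mitochondrial limit and 31 and 13 had too few genes. In each library the barcodes with the highest Scrublet doublet scores were then left out, at 0.8% per 1000 barcodes, which removed 109 Ctrl and 146 RES barcodes. The kept cells had a median of 4506 UMIs and 1814 genes in Ctrl and 6365 UMIs and 2272 genes in RES, with a median mitochondrial share of 2.43% and 2.56%. Deposited barcodes ranged up to 33804 UMIs in Ctrl and 44791 in RES, so doublets that the score missed can remain among the deepest cells.

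Counts of both libraries were scaled to 10000 per cell, log-transformed and clustered together with scanpy 1.11.5 (2000 variable genes, 30 principal components, 15 neighbours, Leiden resolution 1, no integration of the libraries), which gave 20 clusters. Clusters were named from 24 marker lists fixed before the data were examined. The rule that turns marker levels into a name was set after the data were seen: the best list had to lead the next by 0.8 on the log2 scale and to have at least 3 markers seen in 10% of the cells. No other list could have more markers than the best list among the 10 leading genes of the cluster. Clusters 8, 11 and 12 stayed unnamed under this rule. They held 4.05%, 2.88% and 4.76% of Ctrl cells and 0.922%, 0.648% and 4.39% of RES cells. The broad class of monocytes and macrophages joins the classical monocyte, nonclassical monocyte and monocyte-derived macrophage classes with cluster 12. It was defined after the narrower classes proved to move with the clustering.

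With 1 library per group there was no test, p-value or standard error of a difference. Raw UMIs were summed per library over all kept cells and over each class with at least 100 cells in each library, and sums were given as CPM. The interval of a ratio is the exact conditional binomial interval, that of a UMI sum the exact Poisson interval, and that of a share the exact Clopper-Pearson interval, at the 95% level. Newcombe's interval was used for a difference of shares. All of them cover counting error only and not variation between mice or preparations. A count of 0 was given a limit of 3 counts.

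Named genes followed a rule fixed before the data were examined. For each of 8 comparisons (all kept cells, the broad class and 6 narrower classes) they were the 10 highest and 10 lowest by log2 ratio with a pseudocount of 10 CPM, among genes with at least 100 CPM in either library. Mitochondrial, ribosomal protein, haemoglobin, Xist and Y-linked genes were left out of the ranking, and so were markers of other classes only within a class. From each of 27 gene lists fixed beforehand, up to 4 examples were named: the 2 highest and 2 lowest members with at least 20 CPM in either library. Members 1.5-fold or more apart were counted as higher or lower. A list's median log2 ratio was set against the 2.5 and 97.5 percentiles of 10000 random lists of the same size, matched on mean expression in 20 bins, as a description of these libraries. Where the list had fewer than 3 measured members no median was given. Some genes that these rules select are not reported here. Of the lists, Ifi30 and Clec7a were not analysed here.

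Shares of cells with a UMI were taken after thinning each cell to 1000 UMIs and leaving out shallower cells, for genes listed beforehand, and for Arg1, Spp1 and Cxcl9, which were chosen after their sums were seen. The share in a class chosen as background is given beside each gene except Clec4f and Timd4. For Cd163 and Marco that share is unthinned, and for Ccr2 the chosen class also expresses the gene. Gene positions come from the GENCODE M21 annotation of GRCm38, where all 105 named genes of the 8 comparisons had a position.

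The functions for ratios, intervals, named genes and list medians were tested on independent Poisson counts drawn from the means of these libraries with 200 genes altered by known folds. In the simulation of monocytes and macrophages (5684 genes) 95.6% of intervals held the true ratio and 20 of 20 named genes were truly altered. In that of NK-like cells (5737 genes) the share was 95.2%, again with 20 of 20. Of 100 unaltered lists, 3 lay outside the random range in each simulation, and the altered list lay at percentile 100. The intervals assume the same Poisson counting, so the simulations check the code alone. They hold no variation between mice and no genes that vary together, as members of a real list can.

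Shares of the compared classes, ratios of the genes named by rank and list medians were recomputed under 3 other cell filters. In the first, the gene and mitochondrial limits were lifted but the doublets still left out (3582 Ctrl and 4132 RES barcodes). The others used at least 500 genes and at most 5% mitochondrial UMIs, or left out no doublets. Ratios of genes not named by rank were not recomputed. Clustering was repeated at Leiden resolution 0.5 and 2, with each library on its own and, as an alternative added after seeing the data, without the 645 genes that differed 1.5-fold between the libraries in monocytes and macrophages. Sums were also scaled by edgeR 4.0.16 TMM factors, computed as means of per-cell CPM, computed with mitochondrial and ribosomal protein genes out of the total, and thinned to 1000 UMIs per cell. The ranking was repeated with a pseudocount of 1 and 50 CPM and a floor of 20 CPM, list medians with all members seen in both libraries and with a floor of 100 CPM, and shares of positive cells at 500 and 2000 UMIs and unthinned. Other tools were Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, statsmodels 0.14.6, igraph 0.11.9 and R 4.3.3.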

Results

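Messenger RNA was counted in single cells of the mouse liver by 10x droplet sequencing of transcript 3′ ends. Leukocytes positive for CD45 and for the integrin CD11b were sorted from C57BL/6 liver mononuclear cells after a Histopaque density gradient. There were 2 libraries: Ctrl, from uninjured mice, and RES, from mice whose liver fibrosis had resolved. Each library pooled the cells of 5 mice, so each group had 1 library and there was no replicate check of any difference between them. The Ctrl library held 20379164 UMIs (unique molecular identifiers, each standing for 1 captured transcript) in 3691 barcodes, and the RES library 34119806 UMIs in 4278 barcodes. After filtering, 3337 Ctrl cells and 4011 RES cells were kept, with a median of 4506 and 6365 UMIs per cell. Levels are UMI sums over the cells of a library, scaled to the UMI total of those cells (CPM). Ratios are RES over Ctrl on the log2 scale, and every interval is a 95% interval that covers counting error only. Each group was 1 library, so library and group cannot be told apart.

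The kept cells were mostly natural killer (NK) cells, monocytes, macrophages and dendritic cells, and RES held a larger share of monocytes and macrophages. NK-like cells, innate lymphocytes that kill stressed cells and carry CD11b on part of their population, made up 44.8% of Ctrl cells (43.1 to 46.5, exact Clopper-Pearson interval) and 36.4% of RES cells (34.9 to 37.9). Monocytes and macrophages, pooled into a broad class that was set after the clusters were seen, made up 32.0% (30.4 to 33.6) and 49.8% (48.2 to 51.3), a difference of 17.8 percentage points (15.53 to 19.96). For each monocyte or macrophage there were 1.40 NK-like cells in Ctrl and 0.731 in RES. Among the cells outside the broad class, the NK-like share was 65.8% in Ctrl and 72.5% in RES. Conventional type 2 dendritic cell (cDC2)-like cells, which present antigen to helper T cells, made up 8.21% (7.30 to 9.19) and 4.94% (4.29 to 5.65). The size of this difference was unstable: -3.27 percentage points here, -1.69 at Leiden resolution 2 and -8.33 with each library clustered on its own, where no RES cluster was named so, and at resolution 0.5 the class was not named. B cell-like cells were at 3.27% and 3.04%, a difference of -0.225 percentage points (-1.04 to 0.574) that was not detectable at this depth. With each library clustered on its own it was 1.53 (0.837 to 2.22), so its sign depended on the clustering. The smaller classes were T cell-like (1.02% and 1.17%), cDC1-like (1.98% and 1.15%), migratory dendritic cell-like (0.959% and 0.773%) and plasmacytoid dendritic cell-like cells (0.749% and 0.349%). Hepatocyte-like barcodes, parenchymal cells that the sort should exclude, numbered 22 in RES and 0 of 3337 in Ctrl, which allows a Ctrl share of up to 0.0899%. They had a median of 712.5 UMIs, formed cluster 19 and came from RES alone.

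**Figure D1:**
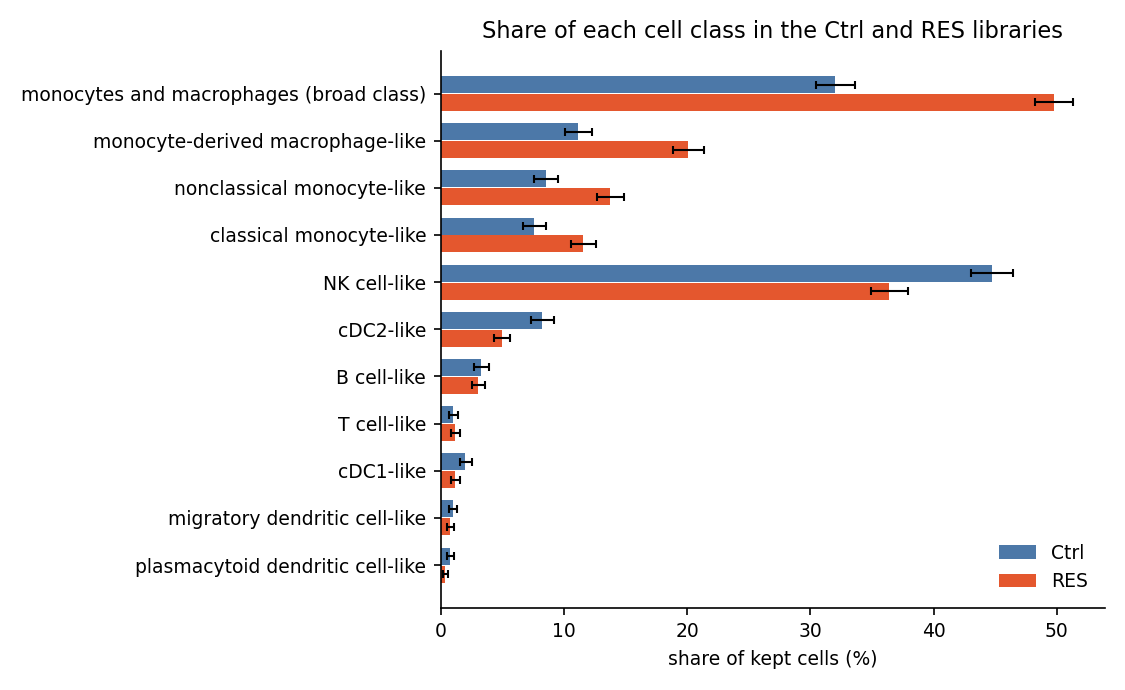
Share of kept cells in each named class (percent of all kept cells) in the Ctrl and RES libraries, with exact 95% binomial intervals that cover counting error only. Monocytes and macrophages stood at 32.0% in Ctrl and 49.8% in RES, and NK-like cells at 44.8% and 36.4%.

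Within the broad class, cells named by their markers belonged to 3 narrower classes. Nonclassical monocyte-like cells (cluster 4), which patrol the vessel wall, made up 8.51% of Ctrl cells (7.59 to 9.51) and 13.8% of RES cells (12.7 to 14.9). Classical monocyte-like cells (clusters 5 and 6), recruited from blood into injured tissue, made up 7.58% and 11.5%. Monocyte-derived macrophage-like cells (clusters 9 and 15) made up 11.1% and 20.1%. Cluster 9 held 351 of the 372 Ctrl cells of this last class and cluster 15 held 726 of its 805 RES cells, and a cluster mostly of 1 library may be that library and not a cell type. The shares of these last 2 classes were unstable: with Leiden resolution 2 the difference in classical monocyte-like cells was -1.19 percentage points in place of 3.96, and across the other clusterings and cell filters the macrophage-like class held between 17 and 98 Ctrl cells. Clustered without the 645 genes that differed 1.5-fold between the libraries in monocytes and macrophages, the macrophage-like share was 2.94% in Ctrl and 15.8% in RES. That clustering gave 44.5% and 36.2% for NK-like cells and 31.3% and 48.8% for monocytes and macrophages. Clusters 8, 11 and 12 stayed unnamed, with 135, 96 and 159 Ctrl cells against 37, 26 and 176 RES cells. Cluster 12, led by Lyz2 and Ace, was counted in the broad class only. Effects of the sort, the density gradient and the deeper RES library on these shares were not tested.

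The marker list of resident Kupffer cells includes C1qa, a leading gene of cluster 9. Its members Clec4f, Timd4, Cd163 and Marco were almost absent from the broad class, and Trem2 was seen in more RES cells. Cells were thinned to 1000 UMIs for this comparison, which left out 106 Ctrl and 53 RES cells of the whole data set. Clec4f, a Kupffer cell lectin, and Timd4, a receptor for dying cells on resident macrophages, were then seen in 0 of 1048 Ctrl and 0 of 1980 RES monocytes and macrophages, which allows shares with a UMI of up to 0.286% and 0.152%. Unthinned, Clec4f was seen in 2 cells of each library and Timd4 in 2 Ctrl cells and 1 RES cell. Trem2, a lipid-sensing receptor of macrophages in injured liver, had a UMI in 5.15% of thinned Ctrl cells (3.89 to 6.67) and 11.4% of thinned RES cells (10.0 to 12.9), against 25.1% and 49.4% unthinned. In NK-like cells, which should lack Trem2, the thinned shares were 0.0683% and 0.276%. Ccr2, the receptor that draws monocytes out of the bone marrow, was seen in 49.4% and 50.5% of thinned cells (75.7% and 73.8% unthinned), with no direction that held across depths. NK cells also express Ccr2, so their 24.6% and 23.9% are not a background level. Cx3cr1, the fractalkine receptor of monocytes, was seen in 38.7% and 31.0% of thinned cells (80.0% and 78.9% unthinned), with 6.15% and 5.31% in NK-like cells. The scavenger receptor genes Cd163 and Marco were seen in 0 or 1 thinned cell of each library. Unthinned, Marco was seen in 0 Ctrl and 7 RES cells (0.351%, against 0.205% in NK-like cells), and Cd163 in 0.655% and 1.20% (NK-like 1.14% and 0.890%). The median unthinned depth was 7200 UMIs in Ctrl and 9529.5 in RES monocytes and macrophages, and 3257.5 and 4041.5 in NK-like cells.

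The question in monocytes and macrophages was which transcripts differed between uninjured and resolved liver. Spp1, Arg1, Fn1 and most glycolysis genes were higher in RES, and interferon-induced genes and antigen presentation genes were lower. The class held 1068 Ctrl cells and 1996 RES cells. Spp1 was at 12.5 CPM in Ctrl and 964 CPM in RES (log2 ratio 6.26, 5.98 to 6.57); Spp1 encodes osteopontin, a secreted matrix phosphoprotein. Arg1 was at 126 CPM in Ctrl and 3376 CPM in RES (log2 ratio 4.75, 4.66 to 4.84), where Arg1 encodes arginase, which splits arginine to ornithine. Fn1, the matrix glycoprotein fibronectin, was at 725 CPM in Ctrl and 5096 CPM in RES (log2 ratio 2.81, 2.77 to 2.85). In the opposite direction, Cxcl9, a chemokine for activated T cells that interferon gamma induces, was at 588 CPM in Ctrl and 11.1 CPM in RES (log2 ratio -5.73, -5.93 to -5.53).

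The 10 genes ranked highest in RES also held Thbs1, encoding the matricellular protein thrombospondin, at 11.8 CPM in Ctrl and 136 CPM in RES (log2 ratio 3.54, 3.23 to 3.85). Ltc4s, the leukotriene C4 synthase, had a log2 ratio of 3.77 (3.46 to 4.09), and Emp1, an epithelial membrane protein, one of 4.58 (4.13 to 5.07). The others were the nuclear lamina gene Lmna (3.77), the small GTPase gene Rhoc (3.48), the actin-associated gene Rai14 (3.84) and AA467197 (3.22), the mouse counterpart of a mitochondrial protein gene induced by inflammatory signals. Among the 10 ranked lowest, Cxcl10, a second chemokine for activated T cells, was at 392 CPM in Ctrl and 30.9 CPM in RES (log2 ratio -3.66, -3.79 to -3.54). Gbp2 and Gbp5, guanylate-binding proteins that act against intracellular microbes, had ratios of -3.84 (-4.01 to -3.69) and -3.57 (-3.82 to -3.34). Ccl5, a chemokine of T and NK cells, was at 371 CPM in Ctrl and 48.4 CPM in RES (log2 ratio -2.94, -3.04 to -2.83). The interferon-induced genes Isg15 (-2.37), Ifi205 (-2.94) and Fam26f (-2.56) and the myeloid surface protein genes Ly6i (-2.45) and Slamf8 (-2.17) completed the group.

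**Figure D2:**
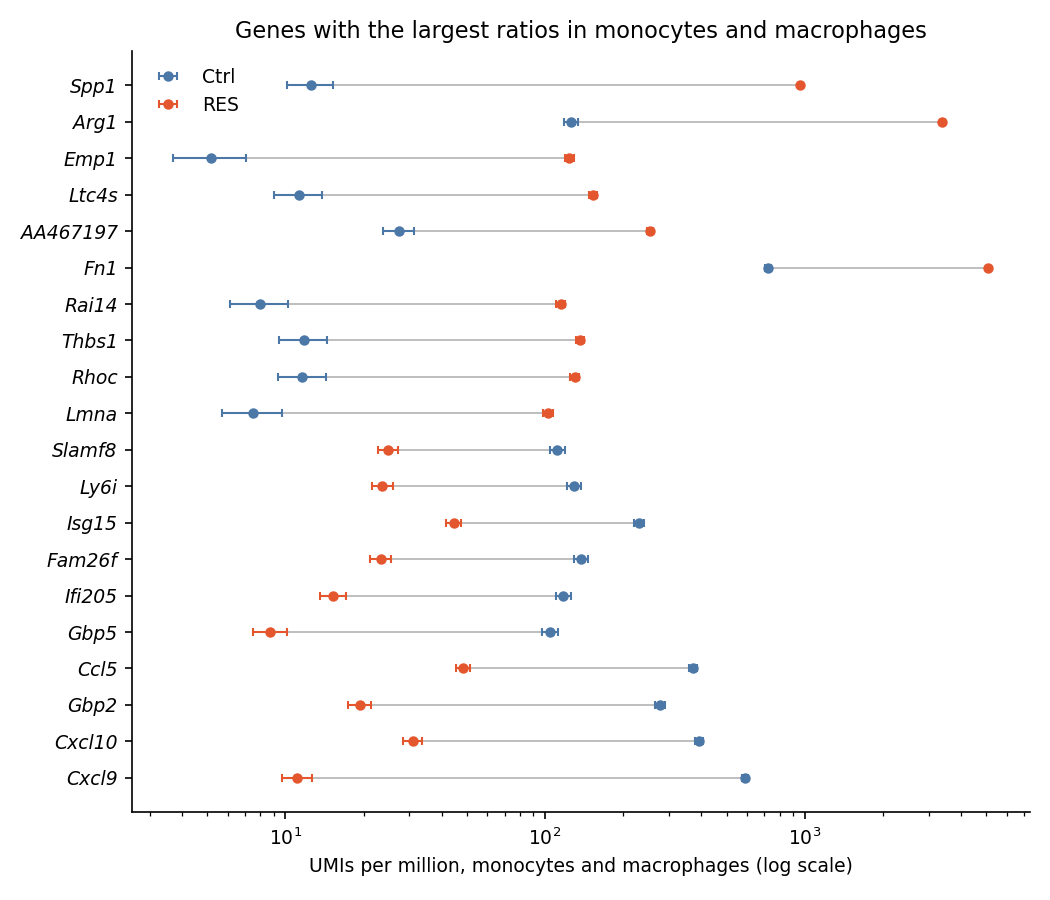
CPM on a log scale in Ctrl and RES for the 10 highest and 10 lowest ranked genes in monocytes and macrophages, with 95% intervals that cover counting error only. Spp1 had the widest gap toward RES, a log2 ratio of 6.26, and Cxcl9 the widest toward Ctrl, one of -5.73.

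On the GRCm38 assembly (mm10), Arg1 lies on chromosome 10, 24915221 to 24927484, Spp1 on chromosome 5, 104435118 to 104441050, and Fn1 on chromosome 1, 71585520 to 71653200. Cxcl9 and Cxcl10 are neighbours on chromosome 5, at 92321347 to 92328079 and 92346638 to 92348889. Tsc22d3 lies on chromosome X, 140539528 to 140600659.

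Interferon-induced genes were lower in RES monocytes and macrophages without exception among the measured members. All 15 measured members of the interferon gamma response list were at least 1.5-fold lower. Their median log2 ratio was -2.02, against -0.16 to 0.26 for the central range of 10000 random lists matched on expression, and it was -3.57 with members of at least 100 CPM alone. Besides Cxcl9, the lowest was Gbp4 at 33.2 CPM in Ctrl and 1.94 CPM in RES (log2 ratio -4.09, -4.63 to -3.60), and the closest to level were the checkpoint ligand gene Cd274 (-0.64) and the autophagy-linked GTPase gene Irgm1 (-1.40). All 16 measured members of the type I interferon list were also lower, with a median of -1.66 (random -0.14 to 0.20), from Ifit3 (-2.39) and Isg15 (-2.37) to Ifi204 (-0.93) and Ifi27l2a (-1.11).

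Antigen presentation genes were lower as well. Of 8 measured members of the MHC class II list 7 were at least 1.5-fold lower, with a median of -1.07 (random -0.21 to 0.25). Ciita, the master regulator of class II transcription, was at 143 CPM in Ctrl and 43.3 CPM in RES (log2 ratio -1.73, -1.86 to -1.60). The class II chains H2-Eb1 (-1.21) and H2-Aa (-1.01) were lower, and Ctss, the protease that trims the invariant chain, had a ratio of -0.02. The lower class II median of this pooled class depended on clusters 6 and 9: without them it was 0.13. Cluster 6 was led by interferon-induced genes, and cluster 9 by Cxcl9 and the complement genes C1qa, C1qb and C1qc. Of 13 measured members of the MHC class I list 9 were lower, with a median of -0.83 (random -0.18 to 0.22). They included Nlrc5 (-1.63), the class I transcription activator, and Tap1 (-1.56), the peptide transporter, while B2m (-0.33) and the trimming peptidase Erap1 (0.14) were closer to level.

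Most glycolysis, profibrotic and scar-associated genes were higher in RES monocytes and macrophages. Of 17 measured genes of glycolysis and hypoxia 13 were at least 1.5-fold higher and 0 lower, with a median of 1.27 (random -0.14 to 0.20). Slc2a1, the main glucose transporter, was at 13.8 CPM in Ctrl and 59.0 CPM in RES (log2 ratio 2.09, 1.81 to 2.39), and Bnip3, a hypoxia-induced mitophagy receptor, had a ratio of 1.94, while the hexokinase genes Hk1 (0.19) and Hk2 (0.13) were close to level. Of 12 measured profibrotic mediators 7 were higher and 1 lower, with a median of 2.49 (random -0.18 to 0.23). That median was 1.35 with all members seen in both libraries and 1.62 with members of at least 100 CPM. Vegfa, the endothelial growth factor, was at 2.20 CPM in Ctrl and 52.8 CPM in RES (log2 ratio 4.59, 3.90 to 5.37); Tgfb1, the central fibrogenic cytokine, had a ratio of -0.16, and the chemokine Ccl17 one of -4.62. Of 15 members of the scar-associated and lipid-associated macrophage list 11 were higher and 0 lower (median 1.09, random -0.17 to 0.21). Plin2, which coats lipid droplets, was at 162 CPM in Ctrl and 634 CPM in RES (log2 ratio 1.96, 1.88 to 2.05), whereas Apoe (-0.05) and Fabp5 (0.01) were level.

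Genes of alternative activation were higher in RES too: 10 of 13 were higher and 1 lower, with a median of 1.06 (random -0.17 to 0.25). Beside Arg1, Igf1, a growth factor, was at 14.7 CPM in Ctrl and 95.9 CPM in RES (log2 ratio 2.70, 2.43 to 2.99), and Il1rn, the interleukin-1 receptor antagonist, was lower at -0.71. Of 10 matrix degradation genes 5 were higher and 0 lower (median 0.60, random -0.20 to 0.24), among them Timp1, an inhibitor of matrix proteases, at 1.16 CPM in Ctrl and 56.4 CPM in RES (log2 ratio 5.60, 4.67 to 6.73) and Mmp19 (2.98), while Mmp14 (-0.03) was level. Of 11 efferocytosis and scavenging genes 4 were higher (median 0.54, random -0.18 to 0.25), including Stab1 (1.62) and the fatty acid transporter Cd36 (1.55), with C1qa at -0.31 and Axl at -0.29.

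The chemokine list split: 7 of 13 members were higher and 4 lower, with a median of 1.07 (random -0.17 to 0.25). Ccl2, which recruits monocytes, was at 19.1 CPM in Ctrl and 133 CPM in RES (log2 ratio 2.79, 2.55 to 3.04), and Ccl7, of the same family, was seen with 2 UMIs in Ctrl (log2 ratio 6.75, 4.89 to 9.80). Inflammatory mediators had no common direction (median 0.09, random -0.20 to 0.27). The lipopolysaccharide co-receptor Cd14 (2.36) and the cytokine Osm (2.28) were higher, and Il18 (-0.69) and Tnfaip2 (-0.67) were lower. Of 16 adhesion and trafficking genes 3 were higher and 2 lower (median -0.14, random -0.15 to 0.18), with the chemokine receptor Ccr1 (2.78) at the upper end and Itgax (-0.78) and Icam1 (-0.62) at the lower.

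Complement genes (median 0.20, random -0.16 to 0.24) ranged from the anaphylatoxin receptors C5ar1 (2.59) and C3ar1 (1.88) to factor B, Cfb (-2.82). Lipid and cholesterol genes were slightly to the RES side (median 0.22, random -0.14 to 0.21), with the sterol carrier gene Npc2 at -0.59. Iron and haem genes (median -0.02, random -0.18 to 0.26) and Kupffer cell regulators (median 0.00, random -0.18 to 0.24) were within the random range. The haem oxygenase gene Hmox1 had a ratio of 0.44, within 1.5-fold. The transcription factor gene Rbpj (1.71) was higher, and the iron-recycling regulator Spic (-1.37) was lower. Innate sensing genes lay slightly low (median -0.23, random -0.17 to 0.25), with Tlr4 at 1.14 against Nod1 at -0.85 and Tlr7 at -0.66. Antimicrobial genes were within the random range (median 0.05, random -0.19 to 0.26), with the oxidase subunit Ncf1 at 0.65 and Acod1, which makes itaconate, at -1.76. Alarmins and granule proteins were above it (median 0.31, random -0.22 to 0.27), with S100a8 at 3.40 and S100a10 at 1.08. Inhibitory receptors had a median of -0.28 (random -0.22 to 0.27), with Havcr2 at -1.18; with members of at least 100 CPM alone that median was 0.0033. Of 5 cytotoxic effector genes detected here 4 were lower (median -2.06, random -0.37 to 0.52), including Klrk1 (-2.47) and Nkg7 (-1.26), which are NK cell genes and can reach this class as free RNA.

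The lists of handling and reference genes had medians within the random range. Immediate-early genes, which tissue dissociation induces, had a median of 0.15 (random -0.15 to 0.19), with Ier3 at 1.30 and Dusp1 at 0.79. Heat-shock genes had a median of 0.19 (random -0.18 to 0.23), with Hspa1b at 1.55. Housekeeping genes had a median of 0.16 (random -0.18 to 0.22), and the glycolytic members Pgk1 (1.34) and Gapdh (0.95) stood above Actb (-0.13). The Y-linked genes measured had a median of -0.06 (random -0.39 to 0.48). The sort markers were not level. Itgam, which encodes CD11b, was higher in RES, at 258 CPM in Ctrl and 503 CPM in RES. Ptprc, which encodes CD45, was lower, at 1923 CPM in Ctrl and 1279 CPM in RES. In all, 9 of 26 lists lay above the random range, 7 below it and 10 within it.

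Under the clustering that kept 645 genes out and under each other setting tried, the 20 named genes kept their direction in monocytes and macrophages. The shares of cells with a UMI, chosen for these genes after their sums were seen, ran the same way after thinning. Arg1 was seen in 1.24% of Ctrl cells (0.662 to 2.11) and 33.9% of RES cells (31.9 to 36.1), against 2.06% and 43.5% unthinned, with 0.342% and 2.69% in thinned NK-like cells. Spp1 was seen in 0.668% and 13.9% (2.15% and 28.7% unthinned), with 0.342% and 2.21% in NK-like cells. Cxcl9 was seen in 8.87% and 0.253% (14.1% and 0.401% unthinned), with 0.205% and 0.069% in NK-like cells.

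NK-like cells, compared to ask whether the difference extended to lymphocytes, held 1494 Ctrl and 1460 RES cells in clusters 0 to 3. Tsc22d3, which encodes the glucocorticoid-induced leucine zipper protein, was at 128 CPM in Ctrl and 233 CPM in RES (log2 ratio 0.87, 0.737 to 1.001). Ifng, the interferon gamma gene itself, was at 137 CPM in Ctrl and 96.5 CPM in RES (log2 ratio -0.51, -0.66 to -0.35).

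The highest ranked gene in RES NK-like cells was the long noncoding RNA AC160336.1 at 83.8 CPM in Ctrl and 185 CPM in RES (log2 ratio 1.14, 0.98 to 1.30). After it and Tsc22d3 came Zfp36l2 (0.74), which destabilises messenger RNA, the phosphatase gene Dusp2 (0.70) and the Mediator subunit gene Med30 (0.67). Pfn1, an actin monomer-binding protein, was at 1782 CPM in Ctrl and 2659.6 CPM in RES (log2 ratio 0.58, 0.54 to 0.61). Ubb (0.56), which encodes ubiquitin, Anxa1 (0.52), an anti-inflammatory annexin, Emb (0.51) and Rsrp1 (0.51) were the remaining genes of the highest 10, each within 1.5-fold. At the lower end were Mir142hg (-0.62), the host transcript of a leukocyte microRNA, the adhesion molecule gene Icam1 (-0.59), Gbp4 (-0.51), and Cd74 (-0.61), the class II invariant chain. Nrip1 (-0.48), Wdr89 (-0.47), Ubash3b (-0.46) and Fubp1 (-0.43) closed the list.

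Of 12 measured interferon gamma response genes in NK-like cells 2 were at least 1.5-fold lower and 0 higher. Their median was -0.24 (random -0.15 to 0.10), with Igtp at -0.74 and Cxcl10 at -1.03, and with Socs1 at 0.16 and Ifi47 at 0.06. The 5 measured type I interferon genes had a median of -0.23 (random -0.23 to 0.17), with Isg15 lowest at -0.76. MHC class II genes, at low levels here, had a median of -0.45 (random -0.20 to 0.18), and MHC class I genes one of 0.12 (random -0.10 to 0.08), with B2m at 0.36. Of 16 cytotoxic effector genes 16 were within 1.5-fold (median -0.09, random -0.08 to 0.07), from Klrd1 (0.20) to the chemokine gene Xcl1 (-0.37) and Ifng. After thinning, Gzma was seen in 96.7% and 97.7% of NK-like cells and Gzmb in 38.7% and 35.7% (Gzmb 63.5% and 67.7% unthinned, so its direction depended on depth). In nonclassical monocyte-like cells, which should lack granzymes, thinned Gzma was at 3.97% and 3.88%, and Gzmb in 0 of 277 and 0 of 541 cells; their unthinned medians were 4424.5 and 4884 UMIs.

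All 14 measured glycolysis genes were within 1.5-fold in NK-like cells, with a median of 0.10 (random -0.13 to 0.07) and the largest ratio 0.35, for the enolase gene Eno1. Adhesion genes had a median of 0.06 (random -0.09 to 0.07). The chemokine receptor gene Cxcr4 was higher at 25.6 CPM in Ctrl and 65.5 CPM in RES (log2 ratio 1.36, 1.07 to 1.65), and Itga4, an integrin chain, had a ratio of -0.38. Immediate-early genes had a median of 0.13 (random -0.10 to 0.09). Macrophage genes were also higher in the RES NK-like cells but at low levels: Fn1 was at 5.08 CPM in Ctrl and 62.7 CPM in RES, Arg1 at 2.44 CPM in Ctrl and 22.7 CPM in RES and Spp1 at 6.58 CPM in Ctrl and 25.8 CPM in RES. The scar-associated list (median 0.30, random -0.17 to 0.15) contains Spp1, and the profibrotic list (median 0.70, random -0.22 to 0.18) contains Spp1 and Fn1. Across the lists with a median, 9 of 24 lay above the random range, 4 below it and 11 within it.

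**Figure D3:**
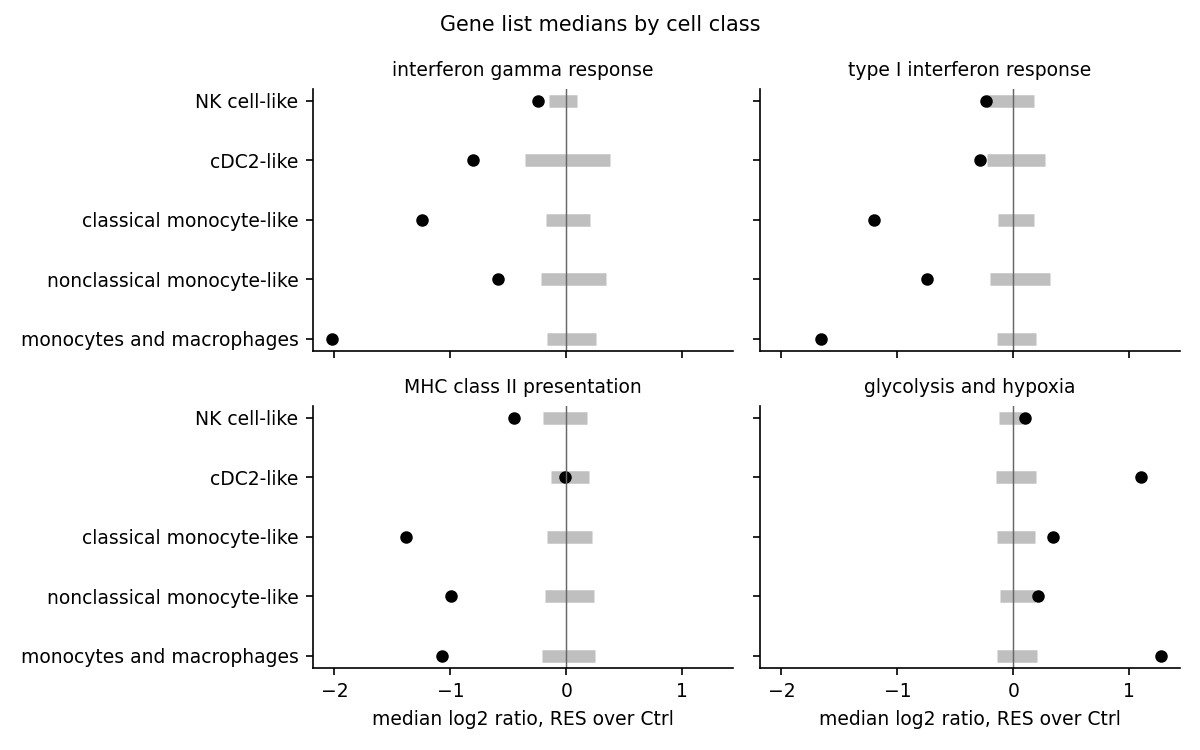
Median log2 ratio of RES over Ctrl (dots) for 4 gene lists in 5 of the compared classes, with the central 95% range of 10000 random lists matched on expression (grey bars). The interferon gamma medians lay on the Ctrl side in every class drawn, from -0.24 in NK-like cells to -2.02 in monocytes and macrophages, and glycolysis stood at 0.10 in NK-like cells against 1.27 in monocytes and macrophages.

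Summed over all kept cells, which mixes composition with expression, the same myeloid genes led. Arg1 was at 63.9 CPM in Ctrl and 2173 CPM in RES (log2 ratio 5.09, 5.01 to 5.17), and Spp1 at 12.2 CPM in Ctrl and 622 CPM in RES (log2 ratio 5.68, 5.49 to 5.87). Cxcl9 was lower in RES, at 278 CPM in Ctrl and 7.13 CPM in RES (log2 ratio -5.28, -5.48 to -5.09). Fn1 had a ratio of 3.26 (3.22 to 3.29), AA467197 of 3.38, the complement receptor gene C5ar1 of 3.19 and Cd14 of 2.87. Cxcl2, a neutrophil chemokine, was at 29.6 CPM in Ctrl and 185 CPM in RES (log2 ratio 2.65, 2.52 to 2.77). Plin2 (2.30), Gatm (2.53), the creatine synthesis enzyme gene, and Ctsl (2.28), a lysosomal protease gene, were also among the highest. Lower genes were Cxcl10 (-3.04), Gbp2 (-2.85), Isg15 (-1.70), the cell cycle gene Ccnd1 (-1.59), Slamf7 (-1.22) and the NK chemokine Xcl1 (-1.06). The plasma cell transcripts Jchain (-1.95) and Igha (-1.06) were lower too. Both were leading genes of unnamed cluster 11, which held 96 Ctrl and 26 RES cells. Such transcripts can also be free RNA in droplets, and the source of the lower sums was not tested.

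Over all cells, 13 of 14 interferon gamma genes and 14 of 15 type I interferon genes were lower, with medians of -1.31 (random -0.17 to 0.14) and -1.10 (random -0.19 to 0.18). With members of at least 100 CPM the interferon gamma median was -2.09. MHC class II and class I lists had medians of -0.63 (random -0.16 to 0.20) and -0.38 (random -0.14 to 0.18), and of 16 cytotoxic genes 8 were lower (median -0.61, random -0.14 to 0.16). The NK-like share was also smaller. So was that of unnamed cluster 8 (135 Ctrl and 37 RES cells), whose leading genes included Xcl1 and Gzmb of the cytotoxic list. Glycolysis and hypoxia (1.11, random -0.14 to 0.18), alternative activation (1.15, random -0.18 to 0.20), scar-associated (1.09, random -0.14 to 0.18) and profibrotic genes (1.70, random -0.18 to 0.22) lay on the RES side. In all, 11 of 26 lists were above the random range, 6 below it and 9 within it.

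In cDC2-like cells (cluster 10, 274 Ctrl and 198 RES cells) most glycolysis and alternative activation genes were higher in RES and interferon gamma genes lower, while class II genes were level. AA467197 was at 15.1 CPM in Ctrl and 418 CPM in RES (log2 ratio 4.79, 4.31 to 5.32). Arg1 was seen with 4 UMIs in Ctrl and 457 in RES (log2 ratio 6.78, 5.42 to 8.66). Gda (3.72), a guanine deaminase gene, the endocytic adaptor gene Dab2 (2.51), Ifitm1 (1.85), the fatty acid-binding protein gene Fabp5 (1.96), the transcription factor gene Cebpb (1.82), the cytokine gene Mif (1.64) and the lectin gene Mgl2 (1.62) followed. Lyz1, a lysozyme gene, was seen with 335 UMIs in Ctrl and 2 in RES (log2 ratio -7.44, -10.49 to -5.58). Further lower genes were Hmgcs1 (-1.24), of cholesterol synthesis, Fam49a (-1.23), Ccnd1 (-1.02), Nav1 (-1.01), Ccl5 (-1.003), Lst1 (-0.96) and Fyb (-0.86). Gm42418 (-0.82) overlaps ribosomal RNA sequence and its counts are uncertain. Arg1, AA467197 and Gda were also leading genes of cluster 15, the macrophage-like cluster of mostly RES cells, whereas Mgl2 and Dab2 were leading genes of cluster 10 itself. Macrophage material in the cDC2-like class was not tested. The ratios of Arg1, AA467197 and Gda, and the alternative activation list that includes Arg1, may therefore not be those of cDC2-like cells alone.

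Of 16 glycolysis genes 13 were higher in RES cDC2-like cells (median 1.10, random -0.15 to 0.19), with Slc2a1 at 2.11 and Hk2 at -0.47. Alternative activation genes had a median of 1.26 (random -0.24 to 0.30) with 7 of 9 higher, including Socs3 (2.33), while Retnla went from 110 UMIs in Ctrl to 1 in RES (log2 ratio -6.84, -12.15 to -4.33). Scar-associated genes had a median of 0.87 (random -0.18 to 0.22). Of 6 interferon gamma genes 5 were lower (median -0.80, random -0.35 to 0.37), with Gbp2 at -1.91, and type I interferon genes had a median of -0.29 (random -0.23 to 0.27). All 11 class II genes were within 1.5-fold, with a median of -0.01 (random -0.13 to 0.20). Clustered each on its own, the RES library gave no cluster named cDC2, so the class rests on the joint clustering.

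In classical monocyte-like cells (253 Ctrl, 463 RES) interferon-induced genes were lower in RES. The metallothionein gene Mt1 was at 30.7 CPM in Ctrl and 166 CPM in RES (log2 ratio 2.43, 2.05 to 2.84) and Cxcl2 at 26.5 CPM in Ctrl and 147 CPM in RES (log2 ratio 2.47, 2.06 to 2.91). Gcnt2 (1.88), the cytokine signalling inhibitor Socs3 (1.75), Cd14 (1.65), the proteoglycan gene Vcan (1.42), Gm9733 (1.24), Clec4e (1.20), Chil3 (1.14) and Dusp1 (1.05) were higher. Cxcl10 (-2.16), Ifi205 (-2.16), Ifit3 (-2.00), Rsad2 (-1.94), Isg15 (-1.64), Ccl5 (-1.76), Cd74 (-1.54), H2-Aa (-1.53), H2-Eb1 (-1.48) and H2-Ab1 (-1.36) were lower. All 12 interferon gamma genes and 17 of 19 type I interferon genes were lower, with medians of -1.24 (random -0.17 to 0.20) and -1.20 (random -0.14 to 0.18). The class II median was -1.38 (random -0.17 to 0.22), alternative activation 1.07 (random -0.23 to 0.30) and glycolysis 0.34 (random -0.14 to 0.19). The class includes cluster 6 (37 Ctrl and 25 RES cells), led by interferon-induced genes, and its class II, Clec4e, Rsad2 and Ccl5 ratios turned direction under at least 1 other clustering or filter. After thinning, Cxcl2 was seen in 1.20% of Ctrl and 10.8% of RES cells (8.70% and 26.6% unthinned; thinned NK-like cells 0% and 0.690%), and Il1b, an inflammatory cytokine gene, in 1.20% and 3.90% (12.3% and 20.7% unthinned; NK-like 0.342% and 0.138%).

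Nonclassical monocyte-like cells (284 Ctrl, 552 RES) had higher levels of most inflammatory mediators in RES and lower class II genes. Fpr2, a formyl peptide receptor gene, was at 23.7 CPM in Ctrl and 157 CPM in RES (log2 ratio 2.73, 2.26 to 3.24), and Hp, which encodes haptoglobin, at 123 CPM in Ctrl and 583 CPM in RES (log2 ratio 2.24, 2.03 to 2.46). Ms4a6d (2.28), Txn1 (1.79), Sod2 (1.44) and Gstm1 (1.55), the lectin gene Clec4e (1.77), Pla2g7 (1.52), Acp2 (1.52) and Serpinb6a (1.37) were higher. Cd74 was at 1527 CPM in Ctrl and 565 CPM in RES (log2 ratio -1.43, -1.52 to -1.34), and Ifi27l2a (-1.64), Serpinb2 (-1.67), H2-Eb1 (-1.56), H2-Ab1 (-1.22), H2-Aa (-0.99), Klra2 (-1.23), the transcription factor gene Mef2c (-0.87) and the prostaglandin-degrading enzyme gene Hpgd (-0.82) were lower. Of 9 inflammatory mediators 7 were higher (median 1.11, random -0.14 to 0.26). Of 7 class II genes 6 were lower (median -0.99, random -0.19 to 0.24). Interferon gamma genes had a median of -0.59 (random -0.22 to 0.34), with 3 of 6 lower and Cd274 higher at 0.62, type I interferon genes one of -0.74 (random -0.20 to 0.32), and glycolysis one of 0.21 (random -0.11 to 0.19). Thinned, Il1b was seen in 9.39% of Ctrl and 18.3% of RES cells (32.4% and 47.1% unthinned) and Cxcl2 in 0.361% and 5.36% (4.58% and 17.9% unthinned), with NK-like shares as given for the classical class.

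The monocyte-derived macrophage-like class set cluster 9 of mostly Ctrl cells against cluster 15 of mostly RES cells, and those clusters are themselves led by Cxcl9 and by Arg1, Fn1 and Spp1, so these genes are not reported as differences within it. No list medians are given for it, since the clustering had already set the libraries apart. The named genes outside the 20 leading genes of each cluster are given below, and their ratios still describe the contrast of these clusters. Timp1 was at 2.99 CPM in Ctrl and 110 CPM in RES (log2 ratio 5.20, 4.27 to 6.33). Hilpda, a hypoxia-induced lipid droplet gene, was at 10.6 CPM in Ctrl and 173 CPM in RES (log2 ratio 4.03, 3.52 to 4.58). Emp1 (4.91), Lmna (4.04), Thbs1 (3.80) and Ltc4s (3.56) were higher. Gbp5 (-5.60), Ccl5 (-4.02), Ly6a (-5.16), Serpina3g (-5.88) and Ccl17 (-5.01) were lower. The Ltc4s and Ccl17 ratios turned direction under at least 1 other clustering or filter.

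B cell-like cells (cluster 16, 109 Ctrl and 122 RES cells) carried transcripts of macrophages, so the ratios of those genes in this class are not those of B cells alone. Lyz2, the macrophage lysozyme gene, was at 6077 CPM in Ctrl and 4859 CPM in RES. Arg1 was at 76.6 CPM in Ctrl and 2133 CPM in RES (log2 ratio 4.80, 4.47 to 5.15), and AA467197 (4.92), Tgm2 (3.98), C5ar1 (4.10), Gatm (3.48), Cd14 (3.12), Cxcl2 (3.11), Basp1 (3.02), Plin2 (2.49) and Igha (4.24) were higher. Retnla, made by alternatively activated macrophages, was seen with 762 UMIs in Ctrl and 1 in RES (log2 ratio -10.04, -15.34 to -7.56). Its Ctrl level here was far above that in Ctrl monocytes and macrophages, so that class as a whole does not account for it. Cxcl9 was seen with 445 UMIs in Ctrl and 0 in RES, at least 205-fold lower against a floor of 3 counts. Cxcl10 had 107 and 1 UMIs (log2 ratio -7.21, -12.52 to -4.70) and Ly6i 136 and 3 (log2 ratio -5.97, -8.26 to -4.39). Gbp2 (-3.66), Isg15 (-2.19), the proteasome activator gene Psme2 (-1.25), AW112010 (-1.31) and Icam1 (-1.22) were also lower. The interferon gamma and type I interferon medians were -1.46 (random -0.17 to 0.33) and -1.73 (random -0.23 to 0.39).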

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

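The tests of free RNA in the RES droplets, of a difference of the whole RES library and of free macrophage RNA in Ctrl NK-like droplets were chosen after the result they bear on was seen, and so were the genes given for barcodes outside the kept cells. The last of these tests first used 1 gene and argued against free RNA, and it was moved to a sum of genes at the same bound after that result was seen.

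Barcodes that the cell filter left out (245 in Ctrl, 121 in RES, median 893 and 1001 UMIs) enter no main comparison, only the setting with the limits lifted, and each of the following signals in them was above its Ctrl level. Haemoglobin genes took 2.80% of their UMIs in Ctrl and 14.8% in RES, a log2 ratio of 2.40 (2.36 to 2.44), against 0.000735% and 0.133% in kept cells. Fn1 had a log2 ratio of 3.23 (2.98 to 3.48), from 158 and 827 UMIs. Arg1 had one of 3.13 (2.39 to 3.95), from 18 and 88 UMIs.

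Arg1, Spp1, Fn1 and glycolysis genes were higher in RES monocytes and macrophages. Thinned to 1000 UMIs per cell, the Arg1 ratio was 5.18, Spp1 6.23 and Fn1 2.67, against 4.75, 6.26 and 2.81 unthinned. Thinning keeps the class labels and the expected share of each gene in a cell, so it could not decide whether depth was the source. In the 552 Ctrl and 1008 RES cells with the lower doublet scores the ratios were 5.96, 5.53 and 2.07. The bound of that test was set for Arg1, whose ratio argues against mixed cells that the score finds as its source. Spp1 and Fn1 were lower there than over the whole class, and mixed cells that the score missed can remain. Free RNA in the RES droplets is argued against by RES NK-like cells, which carried 0.672% of the Arg1 level of RES monocytes and macrophages, 2.68% of Spp1 and 1.23% of Fn1. A shift of the whole RES library as large as the pooled median of 1.27 is argued against for glycolysis by its NK-like median of 0.10. There 0 of 14 genes were higher by 1.5-fold. A smaller shift in all cells is not argued against, since the NK-like median lay above its random range. In B-class cells without a Lyz2 UMI the glycolysis median was 0.48, at percentile 97.4. The pooled median also mixes makeup with expression, and the classical and nonclassical monocyte-like medians were nearer the NK-like one. In cDC2-like cells, outside the broad class, the glycolysis median was nearer the pooled 1.27. Higher glycolysis genes were thus not confined to monocytes and macrophages, though macrophage material in the cDC2-like class was not tested. A difference in state or makeup of the macrophages after fibrosis resolved may be behind a part of the pattern, as a hypothesis found on these data and not itself tested. Differences between the 2 preparations cannot be told apart from the group.

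Interferon-induced genes were lower in RES in several classes. Free macrophage RNA in the Ctrl NK-like droplets is not excluded as a part of the source in NK-like cells: 11 interferon gamma genes summed would need 3.25% macrophage RNA, 4.27 times the 0.760% that the Lyz2 level allows, more than it can supply alone but short of the 5-fold bound set for arguing against it. The 2 clusters with Cxcl10 among their leading genes, 6 and 9, are argued against as the whole source in monocytes and macrophages. Cluster 9 was also led by the complement genes C1qa, C1qb and C1qc. Without clusters 6 and 9 the interferon gamma median was -1.13 over 9 genes (random -0.27 to 0.39) and the type I median -1.12. Cluster 15, with 21 Ctrl and 726 RES cells, stayed in that sum, so unequal makeup of the remaining clusters can be part of these medians. The MHC class II median of the pooled class without clusters 6 and 9 was 0.13, so it depends on those 2 clusters. Nonclassical monocyte-like cells, which hold neither, had one of -0.99. A biological difference in interferon signalling was not tested, and the pool of mice cannot be told apart from the group.

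Arg1 was higher and Cxcl9 lower in RES cells of the B cell class. Macrophage material in that class is the candidate source: the 35 RES cells without a Lyz2 UMI carried 0.983% of the Arg1 level of the whole class, with 4 Arg1 UMIs. The 45 such Ctrl cells carried 0 of the 762 Retnla UMIs. Retnla was far lower in Ctrl monocytes and macrophages than in this class, so its source stays open. Cxcl9 stood at 9.43 CPM in those Ctrl cells against 461 CPM in the whole class. In the same cells the interferon gamma list still lay at percentile 0.02 of random lists, so its genes were also lower in cells without a Lyz2 UMI. A biological difference of Arg1 or Cxcl9 in B cells was not tested apart from these cells.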

How the results depend on the processing

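The clustering without the 645 genes that differed 1.5-fold was chosen after seeing the data, and the lists whose medians are given per class were narrowed after a table of all lists under all settings was seen. Cells are not replicates and each group is 1 library, so none of these settings measures variation between mice. Of 1562 recomputed log2 ratios of named genes, some of which are not reported and not counted here, 1549 kept their direction. The 13 that reversed were 8 in classical monocyte-like and 5 in monocyte-derived macrophage-like cells. The reported genes named by rank in all cells, monocytes and macrophages, NK-like, B cell-like, cDC2-like and nonclassical monocyte-like cells kept theirs under every setting that gave a ratio. Ratios of genes reported only as list examples or chosen by their values were not recomputed. Of 2446 recomputed medians over all lists and comparisons 204 changed sign, and in 43 of these the list had lain outside the random range, 29 of them in monocyte-derived macrophage-like cells; no list median is reported for that class. Differences in shares of cells with a UMI changed sign with depth in 7 of 48 recomputed values, 3 for Gzmb, 3 for Ccr2 and 1 for Cd163, each with a counting interval that held 0 at 1000 UMIs. The NK-like and nonclassical share differences stayed within their counting intervals under every clustering and filter. No cluster was named cDC2 at Leiden resolution 0.5, so that setting gave no value for it. No paired analysis was possible because each group has 1 library and no label pairs them. The RES library was 1.41 times as deep per kept cell, and genes near 1 UMI per class are limited by counting. For the values below the cause was not tested unless the setting itself shows it.

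With the gene and mitochondrial limits lifted and doublets still left out, the share difference was 15.5 percentage points for monocytes and macrophages and 17.3 for the monocyte-derived macrophage-like class. In that class 4 of the 20 named genes were named again, and Ltc4s (-0.10) and Ly6i (0.24) reversed. In classical monocyte-like cells 11 of 20 were named again. With at least 500 genes and at most 5% mitochondrial UMIs, the classical share difference was -1.31 and the macrophage-like one 16.1; 9 and 9 named genes were named again, and classical Clec4e was -0.33. With no doublets left out, the macrophage-like share difference was 16.0, 7 classical and 3 macrophage-like genes were named again, and Ly6i was 0.60 in macrophage-like cells. In classical monocyte-like cells Cd74 was then 0.25, H2-Aa 0.80, H2-Eb1 0.30, H2-Ab1 0.91 and the MHC class II median 0.25.

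At Leiden resolution 0.5, the macrophage-like share difference was 18.0, 9 classical and 4 macrophage-like genes were named again, and Ltc4s was -0.34 in the latter. At Leiden resolution 2, the share differences were -1.69 for cDC2-like, -1.19 for classical monocyte-like and 10.99 for macrophage-like cells; 9 and 9 genes of the last 2 classes were named again, and classical Clec4e was -0.29. With each library clustered on its own, the share differences were -8.33 for cDC2-like cells (no RES cluster was named so), 1.53 for B cell-like (a change of sign) and 13.6 for macrophage-like cells. There 12 classical, 8 macrophage-like and 5 nonclassical genes were named again, and Rsad2 (0.46) and Ccl5 (1.09) in classical and Ccl17 (0.37) in macrophage-like cells reversed. Clustered without the 645 genes, the macrophage-like difference was 12.8 with 13 genes named again, and the type I interferon median of monocytes and macrophages was -1.47.

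With means of per-cell CPM, 13 named genes of all cells and 13 of B cell-like cells were named again; the all-cell medians were -1.02 for interferon gamma and 0.86 for glycolysis, and the profibrotic median of monocytes and macrophages was 2.25. With cells thinned to 1000 UMIs, 10 B cell-like, 10 NK-like, 8 cDC2-like, 13 classical and 13 nonclassical genes were named again, and in monocytes and macrophages the interferon gamma median was -1.68 and the profibrotic one 2.11. Without mitochondrial and ribosomal protein genes in the total, 10 cDC2-like genes were named again. With a ranking floor of 20 CPM, which admits more genes, 11 of all cells, 13 B cell-like, 6 NK-like, 5 cDC2-like, 11 classical and 10 nonclassical genes were named again, and with a pseudocount of 50 CPM 13 macrophage-like ones. With members of at least 100 CPM, which are fewer, the all-cell medians were -2.09 for interferon gamma and 1.60 for alternative activation. In monocytes and macrophages they were -3.57 for interferon gamma, -1.43 for type I interferon, 1.62 for profibrotic and 0.0033 for inhibitory receptor genes. With all members seen in both libraries the profibrotic median was 1.35.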

Other observations

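The genes in this part, and the spread check of the glucocorticoid test, were chosen after their values were seen; both tests had been set before their results. Single genes of monocytes and macrophages stood higher in RES beyond those already named. Ctsd, which encodes the lysosomal protease cathepsin D, was at 187 CPM in Ctrl and 665 CPM in RES (log2 ratio 1.83, 1.75 to 1.91), the tetraspanin gene Cd63 at 24.8 CPM in Ctrl and 84.9 CPM in RES (log2 ratio 1.78) and Adam8, a membrane protease gene, at 6.59 CPM in Ctrl and 35.4 CPM in RES (log2 ratio 2.42, 2.01 to 2.86). The chemokines Ccl9 (306 CPM in Ctrl and 1018 CPM in RES), Ccl6 (949 CPM in Ctrl and 2093 CPM in RES) and Pf4 (26.1 CPM in Ctrl and 87.1 CPM in RES) were higher, while the dendritic cell chemokine Ccl22 was lower (19.9 CPM in Ctrl and 1.94 CPM in RES). Pdgfa, a growth factor for stellate cells, was at 2.33 CPM in Ctrl and 22.1 CPM in RES (log2 ratio 3.25, 2.57 to 4.02). Retnla was higher in RES in this class, at 15.8 CPM in Ctrl and 82.8 CPM in RES (log2 ratio 2.39, 2.13 to 2.67), and lower in RES in the cDC2-like and B cell-like classes.

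Single genes chosen by their values also differed in other classes. In cDC2-like cells Timp1 was at 2.16 CPM in Ctrl and 61.9 CPM in RES (log2 ratio 4.84, 3.59 to 6.49) and Il4ra, the interleukin-4 receptor chain, at 40.1 CPM in Ctrl and 93.8 CPM in RES (log2 ratio 1.23, 0.87 to 1.59), while Ccl4 was lower at 96.6 CPM in Ctrl and 9.55 CPM in RES (log2 ratio -3.34, -4.03 to -2.72). In nonclassical monocyte-like cells the membrane protease gene Mmp14 was at 4.25 CPM in Ctrl and 35.9 CPM in RES (log2 ratio 3.08, 1.99 to 4.43) and complement C3 at 55.9 CPM in Ctrl and 141 CPM in RES (log2 ratio 1.33, 1.01 to 1.68). In classical monocyte-like cells the neutrophil and early myeloid genes S100a8 (2.60 CPM in Ctrl and 78.8 CPM in RES) and Lcn2 (1.04 CPM in Ctrl and 41.4 CPM in RES) were higher, and Axl, a receptor kinase in clearance of dying cells, was lower (30.2 CPM in Ctrl and 8.98 CPM in RES), in a class whose makeup shifted with the clustering. In barcodes left out by the filter, Cxcl9 was seen with 146 UMIs in Ctrl and 0 in RES, at least 27.2-fold lower against a floor of 3 counts.

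As a hypothesis, the RES mice may have had more glucocorticoid signalling, since Tsc22d3 and Fkbp5, both induced through the glucocorticoid receptor, were higher in NK-like cells (0.87 and 0.95 on the log2 scale) and in monocytes and macrophages (0.67 and 2.41). In cDC2-like cells Tsc22d3 was level at 0.05 (-0.17 to 0.28), while Fkbp5 was higher at 1.02. Both genes were higher in each other compared class. The other targets, a list written before the test, had a median of 0.23 over 6 genes in NK-like cells, at percentile 99.7 of random lists, and of 0.38 over 6 genes in monocytes and macrophages, at percentile 94.45. By the criterion as first written, the monocyte and macrophage value lay within the random range and counted against the hypothesis. A check added after that result was seen left out each gene in turn. The medians then ran from -0.01 to 0.48 around a bound of 0.15 in NK-like cells and from 0.13 to 0.62 around a bound of 0.46 in monocytes and macrophages. Across the other comparisons the same list ran from percentile 45.37 in nonclassical monocyte-like cells (median 0.04 over 6 genes) to 99.98 in classical monocyte-like cells (median 0.85 over 3 genes). So few genes decide neither way, and glucocorticoid exposure stays open.

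A second hypothesis was that the 2 pools were collected at different times of day, which could also move Tsc22d3 and Fkbp5. Clock output genes had a median of 0.06 over 3 genes in NK-like cells, at percentile 75.6 of random lists, too few to show that there was none. Only 1 clock gene of the opposite phase reached the floor in NK-like cells, and only 1 clock output gene in monocytes and macrophages, so the test could not be completed and a difference in collection time cannot be told apart from the group.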
